A study of Mus musculus with 8 samples.

How the data were processed

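The series holds expression arrays of 7 mouse embryonic stem (ES) cell lines and 1 ChIP-chip experiment on the parental line E14. Chd1 is a chromatin remodeller with a pair of chromodomains that bind methylated lysine 4 of histone H3. Per the labels, cells were infected with a lentivirus that expresses a short hairpin RNA (shRNA) and mCherry, sorted, and grown as clones on gelatin with serum replacement and LIF. The 3 control lines were uninfected E14 cells, the empty-vector clone E1 and the GFP shRNA clone G8. The 4 Chd1-deficient lines were the clones C1i5, C1i6 and C1i9, made with shRNA 1, and the clone C4i2, made with shRNA 4. Each line was measured on 1 array. The labels do not say whether any line was grown or hybridised more than once, so p-values measure the spread between these 7 lines. No replicate number is shared between groups by the labels, so no pairing was used.

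The expression values are on a log2 scale and were made by the authors with RMA, per the submitters' processing notes; the version and chip definition are not given in the sources used here. RMA corrects background, makes the distributions of the arrays nearly equal and summarises the probes of a probe set, so a shift shared by most transcripts of a line would be removed. The table holds 35557 rows, and the medians of the 7 arrays lay between 6.43 and 6.54. Of these rows, 738 had values identical to those of another row on all 7 arrays. The files used here do not pair the expression probe sets with genes. The Chd1 transcript, the gene lists on the expression arrays, the relation of Chd1 occupancy to expression and the selection of 1 probe set per gene, all chosen before the data were examined, were therefore not analysed here. Every probe set was tested in place of 1 per gene, and the text names at most 2 probe set identifiers in each direction.

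The ChIP-chip file holds Cy5 (Chd1 immunoprecipitation, IP) and Cy3 (DNA without IP) spot intensity and background, 1 normalized intensity per channel and their log2 ratio, all as deposited by the authors, per the file headers. The software and the method of that normalization are not given in the sources used here. The deposited file also gives a score of each probe, its neighbourhood average and a p-value, made by the authors and not used here, and marks the probes that the authors' software placed in bound regions. There were 2 slides and no replicate or dye swap. Of 486982 spots, 12602 were control spots and 147 were excluded by the authors or had no ratio, which left 474233 probes. Median intensity was 434.5 in the IP channel over a background of 41, and 556 in the input channel over a background of 46; 23 probes were saturated. Every deposited log ratio equalled the log2 of the 2 normalized intensities within 1e-05. A second deposited table of this array was not used, because its row numbers match no probe column. The genome build is not given in the sources used here, so coordinates are those of the file.

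Log ratios were centred on the median of each slide (-0.02 on slide 1 and -0.02 on slide 2). A promoter score was the mean centred log2 ratio over probes within 1000 bp of an annotated transcription start, for genes with at least 3 probes. The threshold was the score above which the mirrored negative tail held at most 5% as many promoters. A list's median was set against 10000 random lists of the same size drawn from all scored promoters. With 1 experiment there is no test between conditions, and the SD given with a promoter score is over its probes, not over replicates. Gene labels of the file were matched to current symbols with a RefSeq gene table used for names only (assembly GRCm38.p6), which found 23370 of 24005 labels. Intervals given with shares are 95% Clopper-Pearson intervals, which cover counting error only. A simulation on 15907 promoters shifted 67 by 0.25 log2 units, 67 by 0.5 and 66 by 1. It recovered 10.4%, 77.6% and all of them. It shuffled the probe noise over promoters and set its own threshold, so these rates need not hold for the real data.

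Expression was compared with limma (version 3.58.1 in R 4.3.3; lmFit and eBayes, two-sided) with Benjamini-Hochberg adjustment over all 35557 probe sets and a threshold of 0.05. The first fit compared 4 Chd1-deficient clones with 3 controls. A fit with 3 groups separated the hairpins; it assumes that the lone shRNA 4 clone varies like the other groups. Both hairpins were compared with the same controls, so their agreement was set against 20 simulations without any effect. In data simulated on 35557 probe sets for the first fit, 67 were changed by 0.5 log2 units, 67 by 1 and 66 by 2. Of these, 14.9%, 76.1% and 95.5% were recovered, and 5.34% of calls were false. Many more probe sets were called in the real data, and the adjustment depends on their number, so these rates need not hold there. The number of arrays limits the precision. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

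Before the data were examined, 26 gene lists were fixed: pluripotency, primed epiblast, primitive endoderm, trophectoderm, mesoderm, cardiac muscle, neural, germ line, two-cell-like, fibroblast and feeder, chromodomain and remodeller, heterochromatin, polycomb, ribosomal protein, ribosome biogenesis, p53 target and apoptosis, interferon response, small RNA machinery, imprinted, glycolysis and hypoxia, cell cycle, Wnt, Fgf and LIF pathway target, Y chromosome, bivalent developmental regulator, housekeeping and tissue-restricted. The two-cell-like list had 1 scored promoter and was not used. The rule for named promoters took the 10 highest scores, Chd1, Pou5f1, Nanog and Sox2, and the highest and lowest member of each list; Nanog was not scored here, and 1 list member that the rule takes is not reported here. Other list members named were chosen after their values were seen. For probe sets the rule took the largest changes past the threshold for which all 4 deficient clones lay on one side of all 3 controls, of which the first 2 in each direction are named.

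The alternatives for expression were quantile normalization, centring of arrays, filters on level, eBayes with trend and robust settings, array weights, other thresholds and leaving out each line. Those for ChIP-chip were normexp background correction, windows of 500 and 2000 bp, the median over probes, at least 5 probes, other thresholds and centring on probes far from a start. Chosen after seeing the data were the collapse of identical rows, leaving out 1 block of consecutive identifiers, equal spread of the slides, removal of the brightness trend, removal of saturated spots and the authors' bound regions in place of the threshold.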

Results

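The data comprised 7 expression arrays of mouse ES cell lines, 3 control and 4 Chd1-deficient, and 1 ChIP-chip experiment for Chd1 in parental E14 cells on 2 slides of a promoter tiling array. The design addresses where Chd1 lies in ES cells and how transcript levels differ when Chd1 is depleted by RNA interference. Expression probe sets could not be tied to genes with the files used here, so genes are named for ChIP-chip and probe sets are counted for expression.

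The first question was which promoters carried Chd1 in E14 cells. Among single promoters the strongest signal lay at replication-dependent histone genes, which encode the core histones made during DNA synthesis. Among the gene lists fixed beforehand, ribosomal protein genes stood highest. Of the 10 highest promoter scores, 9 belonged to histone genes and 1 to Rpl4, a protein of the large ribosomal subunit. The highest was H2bc7, a histone H2B gene, at 1.72 ± 0.71 log2 units (SD over 4 probes), with probes starting between 23581145 and 23582609 on chromosome 13. H3c10, a histone H3 gene, scored 1.67 ± 0.29 over 7 probes between 21724598 and 21726042 on the same chromosome. H2ac7, H3c13, H3c8, H2bc18, H3c3, H3c6 and H2ac13 followed, with scores from 1.63 at H2ac7 to 1.43 at H2ac13. Some of these are neighbours that share probes: H2bc7 and H2ac7 had the same highest probe, at 23581731 on chromosome 13. Rpl4 scored 1.505 ± 0.919 over 9 probes on chromosome 9, and its highest probe, at 2.77, lay at position 63971127, upstream of the start.

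Of 15907 promoters with at least 3 probes (median 9), 2097 or 13.2% scored above the threshold of 0.27 log2 units, a 1.21-fold enrichment, and 104 lay below its mirror. A probe in a bound region called by the authors was present in 71.4% of the promoters above the threshold and in 4.04% of the others. Both calls rest on the same array, so this is not independent support. Scores from odd and even probes of a promoter correlated across promoters with Spearman's rho of 0.55 and Pearson's r of 0.60. Promoters are not replicates, and neighbouring probes of the same array do not measure reproducibility between experiments. Promoters whose start shared its window with another gene were above the threshold in 27.8% of cases (95% interval 25.6 to 30.1%), against 11.6% (11.1 to 12.1%) of those alone. Such neighbours share probes, so the same signal can count for more than 1 gene, and the first interval is too narrow. The count fell to 1307 with a 500 bp window, 956 with the median over probes, 968 with a stricter mirrored tail of 1%, and 50 with a score of at least 1.

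Averaged over all genes, the signal was highest 500 to 250 bp upstream of the start, at 0.18 log2 units, and dipped to -0.02 in the first 250 bp downstream. At ribosomal protein genes the same upstream bin reached 0.93 ± 0.12 (standard error over 46 probes of 32 genes). At housekeeping genes the highest bin, 750 to 500 bp upstream, held 0.45 ± 0.08 over 54 probes of 39 genes. Probes of the same gene are not independent, so standard errors over probes are too small. Bivalent developmental regulators, whose promoters carry both lysine 4 and lysine 27 methylation of histone H3 in ES cells, lay at -0.07 ± 0.02 in the bin where the average over all genes was highest.

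**Figure D1:**
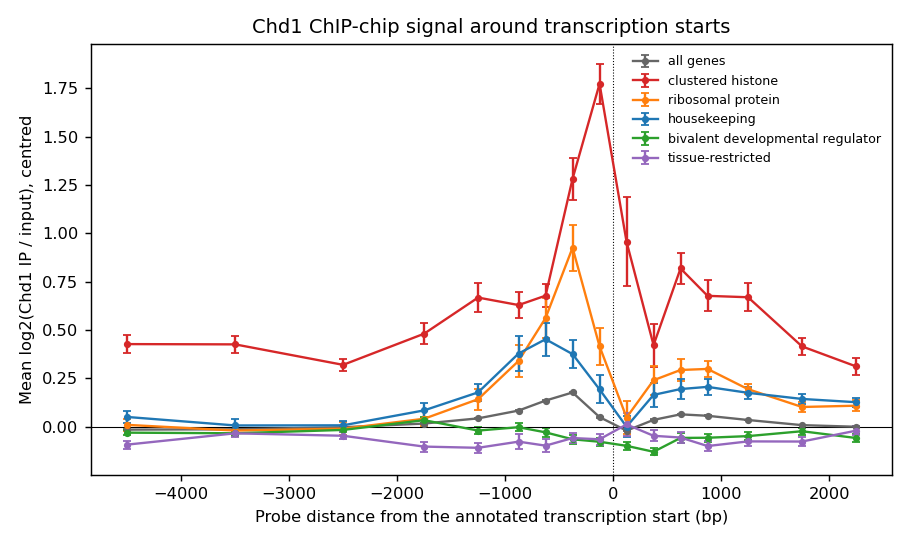
Mean centred log2 ratio of Chd1 IP over input (vertical axis) against probe distance from the annotated transcription start in bp (horizontal axis), with bars for the standard error over probes. A probe near several genes counts once for each. Ribosomal protein genes reach 0.93 between 500 and 250 bp upstream and clustered histone genes, a family chosen after seeing the data, reach 1.77 in the last 250 bp, while bivalent regulators stay near or below 0.

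Genes of the translation machinery stood highest among the lists. Ribosomal protein promoters had a median of 0.29, above all 10000 random lists, and 26 of 48 were above the threshold (54.2%, 95% interval 39.2 to 68.6%). After Rpl4, the leading members were Rps27a at 1.17 and Rpl3 at 1.14, and Rpl10a was lowest at -0.13. Ribosome biogenesis promoters, for genes that make and assemble ribosomal RNA, had a median of 0.22, also above all random lists, with 16 of 34 above the threshold. Nop58, a core protein of box C/D small nucleolar RNPs, led at 0.94 and Polr1a, the largest subunit of RNA polymerase I, scored 0.86, while Bysl was lowest at -0.14. With a 500 bp window the share of ribosomal protein promoters above the threshold was 34.1%, and with the median over probes it was 22.9%. Under the 1% tail it was 29.2%, and that of ribosome biogenesis promoters 23.5%. In these settings the number of all promoters above the threshold fell too. The lower shares alone therefore do not show that the lists stood less high among promoters.

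Other lists also stood high. Housekeeping promoters had a median of 0.16, above all random lists, and 17 of 55 passed the threshold, led by the tubulin gene Tubb5 at 0.95; Hnrnpk was lowest at -0.29. The housekeeping share was 14.5% with a 500 bp window and also with the median over probes, and with normexp the list's median was at percentile 60.1. Cell cycle genes had a median of 0.15 (percentile 99.8) with 7 of 34 above, from Cdc25c, a phosphatase that activates Cdk1, at 0.80 to E2f2 at -0.09. The p53 target and apoptosis list had a median of 0.17 (percentile 99.7) with 7 of 22 above; Ccng1 was highest at 0.53 and Cdkn1a, the p21 inhibitor of cyclin-dependent kinases, lowest at -0.22. Chromodomain and remodeller genes had a median of 0.14 (percentile 97.1) with 3 of 17 above, from Asf1a, a histone chaperone, at 0.40 to Smarca2 at -0.12. Heterochromatin genes had a median of 0.11 (percentile 95.7) with 5 of 22 above; Cbx5, which encodes HP1 alpha, scored 0.70 and Ehmt2 scored -0.14. With a 500 bp window the chromodomain and heterochromatin medians turned negative, at -0.01 (percentile 41.6) and -0.06 (percentile 7.49), and with the median over probes both were near 0 (percentiles 45.2 and 46.6). The heterochromatin list also missed the 95th percentile with at least 5 probes (84.1), normexp (91.3), a 2000 bp window (93.2) and the brightness trend removed (94.8). The shares of these smaller lists moved with the threshold and the score, as did the number of all promoters above the threshold. For p53 targets the share of 31.8% became 13.6% under the 1% tail and 45.5% with centring on probes far from a start, and for cell cycle genes 20.6% became 8.82% with the median over probes and 38.2% with normexp. No chromodomain gene passed with a 500 bp window, the median over probes or the 1% tail, and the heterochromatin share of 22.7% was 9.09% with the median over probes. Of 25 lists with at least 3 scored members, these lists and the translation lists, 7 in all, were above the 95th percentile. The ribosomal protein, ribosome biogenesis and cell cycle medians stayed above it under all 9 alternatives that recompute a score; the p53 list was at percentile 93.4 with a 500 bp window.

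Among pluripotency genes the median was 0.06 (percentile 74.3), within the range of random lists, and 6 of 30 were above the threshold; with a 2000 bp window the median was 0.13 (percentile 99.9). These were Tdgf1, a Nodal co-receptor, at 0.62, and Zfp42 (Rex1) at 0.49, Dppa5a at 0.48, Sox2 at 0.41, Sall4 at 0.38 and Dppa4 at 0.30. The score of Sox2 rested on a narrow signal, with an SD of 0.96 over 8 probes and a highest probe of 2.68 at 34841685 on chromosome 3, 157 bp past the start. Pou5f1 (Oct4) scored 0.21 ± 0.29 over 10 probes, below the threshold, and Chd1 itself 0.01 ± 0.24 over 7 probes. Socs3 was lowest in this list at -0.20.

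The bivalent and the tissue-restricted lists lay low. None of 72 bivalent developmental regulators was above the threshold (95% upper bound 4.99%); their median of -0.06 was below all random lists, from Sox17, an endoderm factor, at 0.11 to Pax5, a B-cell factor, at -0.26. None of 50 tissue-restricted genes was above it (upper bound 7.11%), with a median of -0.06 (percentile 0.02), from the milk protein gene Csn2 at 0.19 to the keratin gene Krt5 at -0.33. The low position of the bivalent list was lost with normexp, which changes the background correction and also leaves out the authors' normalization. There 15.3% of its promoters were above the threshold of that setting, as were 17.4% of all promoters, and its median became 0.10 (percentile 54.7). For the tissue-restricted list, normexp gave 8% above the threshold and a median at percentile 0.12, and a 500 bp window gave percentile 12.6.

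Another 6 lists lay under the 5th percentile. Mesoderm genes had a median of -0.10 (percentile 0.01) with Bmp4 above the threshold at 0.40 and Gsc lowest at -0.34. Trophectoderm genes had a median of -0.08 (percentile 0.35) with none of 16 above, from Gata3 at 0.10 to Tpbpa at -0.14. Germ line genes had a median of -0.06 (percentile 0.62) with none of 18 above, from Prdm1 at 0.23 to Taf7l at -0.24. Neural genes had a median of -0.02 (percentile 3.82), and 2 of 39 were above: Stmn2, a neuronal microtubule regulator, at 0.54 and Tubb2b at 0.47; Nefm was lowest at -0.24. Imprinted genes had a median of -0.04 (percentile 2.77), with 3 of 21 above, from Slc38a4 at 0.38 to Peg3 at -0.13. Polycomb genes had a median of -0.03 (percentile 4.99), with 2 of 24 above, Mtf2 at 0.51 and Eed at 0.40. With normexp, which raised the median of all promoters from 0.03 to 0.09, neural genes lay at percentile 37.1, polycomb genes at 20.8 and imprinted genes, now above most random lists, at 95.7. Polycomb genes lay at percentile 69.4 with a 2000 bp window and 9.37 with at least 5 probes, and imprinted genes at 7.41 with 2000 bp and 7.12 with the median over probes. With a 500 bp window trophectoderm, germ line and imprinted genes were at percentiles 8.41, 10.3 and 16.4. With normexp 22.2% of germ line and 20.5% of neural promoters passed, and no imprinted promoter did with the median over probes or the 1% tail.

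The remaining lists lay between the 5th and the 95th percentile. Primitive endoderm genes had a median of -0.02 (percentile 5.41) with none of 24 above, from Lamc1 at 0.13 to Cited1 at -0.16. Primed epiblast genes also had a median of -0.02 (percentile 12.2), with Otx2 above at 0.35 and Sox3 lowest at -0.13. In the cardiac muscle list (median -0.02, percentile 9.44) Myl4, an atrial myosin light chain, stood at 1.05, and Actc1 at -0.28. Fibroblast and feeder genes (median 0.00, percentile 23.3) ranged from Mgp at 0.19 to Fbn1 at -0.11, and Y chromosome genes (median 0.00, percentile 31.3) from Eif2s3y at 0.18 to Sry at -0.22. Interferon response genes (median 0.02, percentile 31.9) ranged from Irf9 at 0.65 to Psmb8 at -0.33, with 4 of 31 above. Targets of the Wnt, Fgf and LIF pathways (median 0.01, percentile 32.2) ranged from Dusp6, a phosphatase induced by Fgf signalling, at 0.68 to Nkd1 at -0.31. Small RNA machinery (median 0.07, percentile 74.2) ranged from Tarbp2 at 0.55 to Dgcr8 at -0.15, and glycolysis and hypoxia genes (median 0.09, percentile 93.5) from Mif at 0.54 to P4ha1 at -0.12. Some of these lists crossed a bound in an alternative: primitive endoderm with normexp (percentile 2.30), a 2000 bp window (4.98) and at least 5 probes (4.54), the pathway targets with normexp (3.69), and cardiac muscle (3.61) and small RNA machinery (95.6) with 2000 bp.

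**Figure D2:**
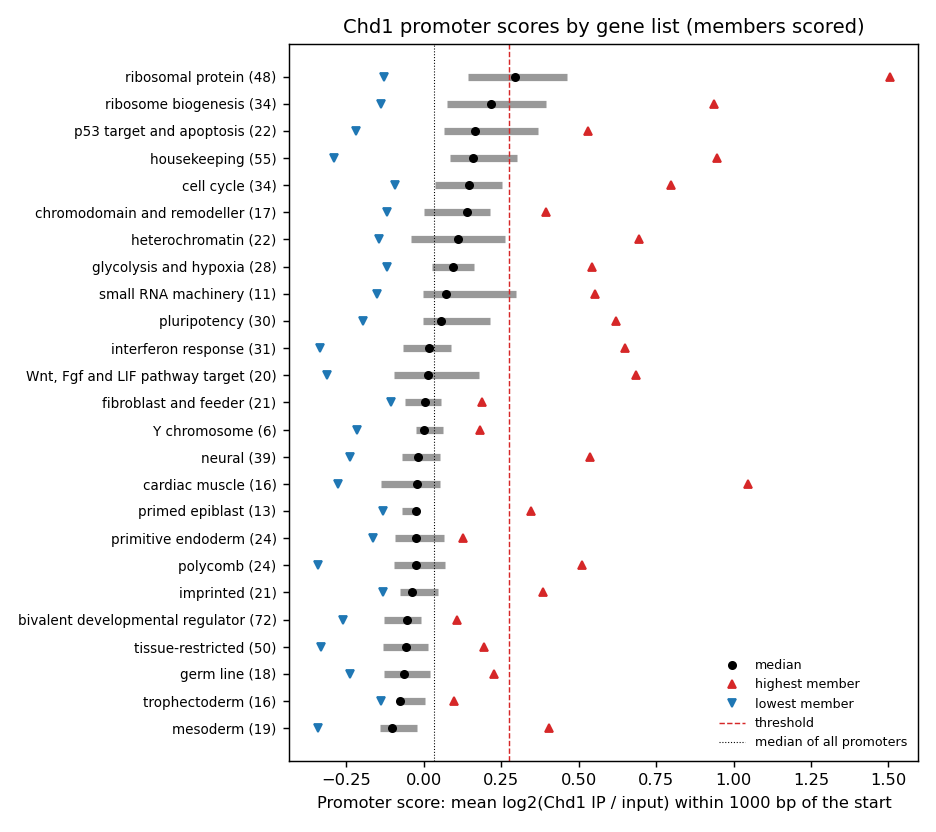
Promoter scores (mean log2 ratio of Chd1 IP over input within 1000 bp of the start, horizontal axis) for 25 gene lists, with the number of scored members in brackets; dots are medians, grey bars the middle quartiles and triangles the highest and lowest member. The ribosomal protein median of 0.29 lies above the dashed threshold of 0.27, and no bivalent or tissue-restricted member reaches it.

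The second question was how transcript levels differed in Chd1-deficient ES cells. The 7 lines separated by group: the first principal component, with 47.1% of the variance, placed the 3 controls between -46.1 and -44.7 and the 4 deficient clones between 25.7 and 52.2. Correlations between arrays were 0.990 to 0.991 among controls, 0.980 to 0.989 among deficient clones and 0.969 to 0.980 between the groups. The number of probe sets more than 2-fold from the median of the other 6 lines was 1157 in E14, 1120 in E1, 1134 in G8, 753 in C1i5, 709 in C1i6, 980 in C1i9 and 1468 in C4i2; for a control, 4 of the other 6 lines are deficient clones, so that median lies nearer to them.

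**Figure D3:**
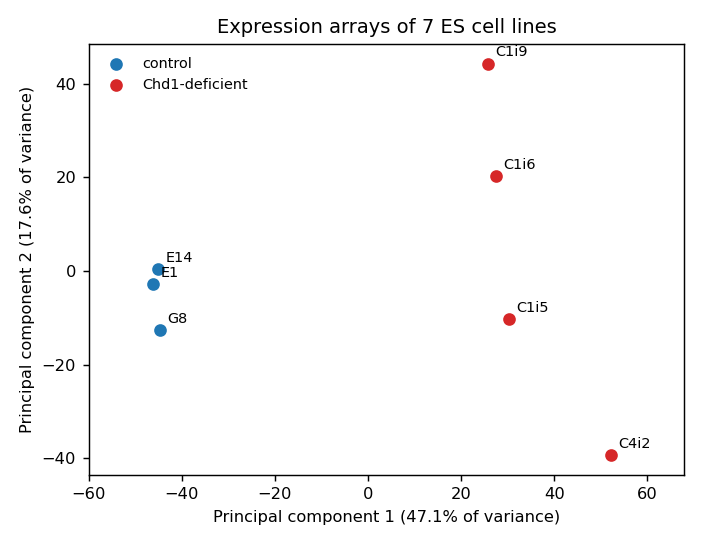
Principal components of the 7 expression arrays (component 1 with 47.1% and component 2 with 17.6% of the variance, in units of the log2 scores), 1 point per line. The 3 controls lie together at the left, and C1i9 and C4i2 lie farthest apart among the deficient clones on component 2.

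Chd1-deficient clones differed from controls at 2947 of 35557 probe sets (limma, adjusted p under 0.05), 1808 higher and 1139 lower. Large differences were mostly rises: 837 probe sets were at least 2-fold higher and 103 at least 2-fold lower. The median change over all probe sets was -0.05 log2 units. The largest rise was at probe set 10363224, from 6.09 ± 0.33 in controls (SD, n = 3) to 12.25 ± 0.60 in deficient clones (SD, n = 4), a change of 6.16 with a standard error of 0.34 (limma adjusted p = 0.000617). Probe set 10531931 rose by 5.21 log2 units (limma adjusted p = 0.00192). The largest fall was at probe set 10490923, from 10.53 ± 0.56 to 8.22 ± 0.39, a change of -2.30 with a standard error of 0.31 (limma adjusted p = 0.00896). Probe set 10419744 changed by -1.84, at the edge of the threshold (limma adjusted p = 0.049995), and it missed the threshold in 7 of 17 alternatives, with adjusted p from 0.00414 to 0.160. At all called probe sets, the 4 deficient clones lay on one side of all 3 controls, which a call on these same 7 values nearly requires. Over all probe sets, called or not, 10.7% had every deficient clone higher and 12.6% every one lower. Chance puts 2.86% of probe sets there in each direction.

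The counts moved when single lines were left out. Fewer arrays lower the precision whichever line is left out, so a fall in calls alone does not show dependence on that line. Without E14, E1 or G8 the probe sets called higher numbered 1005, 859 and 831, and those called lower 371, 327 and 283. Leaving out C1i6, C1i9 or C4i2 gave 606, 620 and 697 lower calls. Of the 2947 probe sets, 2028 were also called without C4i2 and 1265 without the uninfected line.

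The next question was whether both hairpin sequences gave the same changes. With shRNA 1, 1576 probe sets were higher and 697 lower than in controls; in C4i2, 1742 were higher and 936 lower. Simulations without effect set no baseline for calls shared by both hairpins, since probe sets without any effect are rarely called. Of the 2273 probe sets called with shRNA 1, 2251 (99%) changed in the same direction in C4i2. None was called in opposite directions, which the shared controls make less likely. Over all probe sets, 77.3% had changes of the same sign with both hairpins, against 61.4% in simulations without effect, where the shared controls alone make signs agree. Across probe sets, which are not replicates, the changes correlated with r = 0.74, and the simulations gave 0.36. The covariance was 0.171 against 0.0167 in those simulations, a difference of 0.155. The 3 controls cannot be split into parts of at least 2, so part of the agreement may come from the shared controls.

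The shRNA 1 and C4i2 counts also moved with single lines, where fewer arrays again lower the precision. Without E14, E1 or G8, shRNA 1 gave 764, 589 and 568 higher and 168, 129 and 106 lower, and C4i2 gave 1006, 960 and 943 higher and 324, 328 and 332 lower. Without C1i6 or C1i9, shRNA 1 gave 628 and 785 higher and 166 and 190 lower.

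Between the single C4i2 array and the 3 shRNA 1 clones, limma called 190 probe sets higher and 20 lower in C4i2 (adjusted p under 0.05), with the spread of C4i2 taken from the other groups. Hairpin and clone cannot be separated there, since shRNA 4 had 1 clone, and the number of calls changed with the lines included. The higher calls numbered 126 without C1i5, 26 without C1i6 and 57 without C1i9, and the lower calls 29, 0 and 4.

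**Figure D4:**
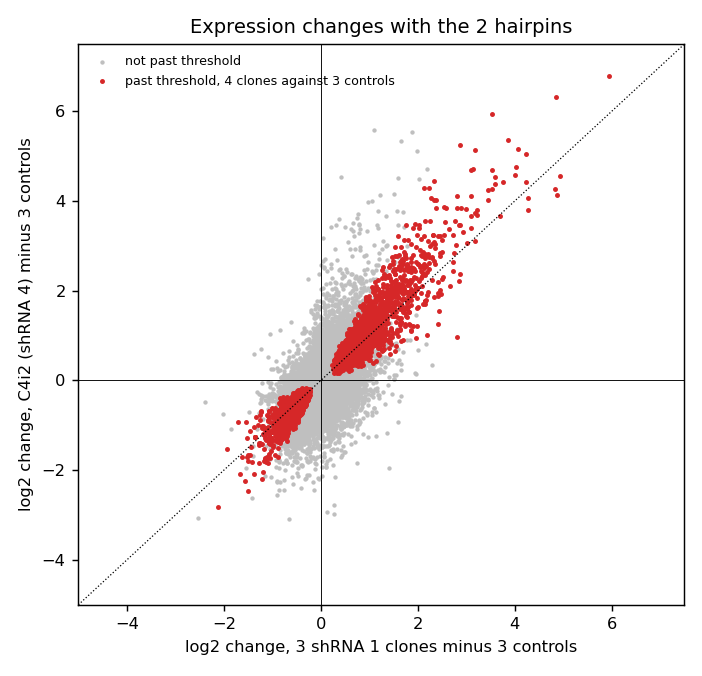
Change in log2 expression against the 3 controls for the 3 shRNA 1 clones (horizontal axis) and for C4i2 (vertical axis), 1 point per probe set; red points passed the threshold in the comparison of all 4 clones with controls. The dotted line marks equal change, and the farthest point, at 5.95 and 6.79, is probe set 10363224.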

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

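All explanations of the expression patterns in this part were tested only after the results they concern had been seen, and the comparison of hairpins was planned.

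The limma comparison of C4i2 with the shRNA 1 clones called 190 probe sets higher and 20 lower in C4i2. C4i2 is a single clone and array, so hairpin and clone are not separated, and without C1i6 the counts were 26 and 0. On the ChIP-chip slides, 53 of 12980 probes with a genomic position and no gene annotation, which entered no promoter score, lay in the authors' bound regions (0.408%, 95% interval 0.306 to 0.534%). That share was the lowest of the annotation classes, which otherwise ran from 0.746 to 3.53%. Dixon's test, run on 9 measures of the 4 deficient clones, found no clone far from the others, but with 4 values it can find only extreme gaps; the 3 controls were not tested.

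The number of calls was compared with other splits of the lines. For all 7 lines, 1 of 35 splits gave as many calls as the real one, namely the real split with 2947, and the highest of the others gave 1. That share of 1 in 35 is under 0.05 and is the smallest that 7 lines can give. It argues against chance assignment of lines to groups but cannot exclude it. For the shRNA 1 clones, 1 of 10 splits gave as many calls as the real 2273 and the highest other gave 0; 10 splits are too few for a share under 0.05.

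Large rises outnumbered large falls, 837 to 103 at 2-fold. Falls hidden near the background are argued against as the whole source, because among the 11852 probe sets with the highest control levels, which had room to fall, 73.6% of 2-fold calls were rises (lower 95% bound 68.2%); the share was 98.9% among those with the lowest control levels, so part of the excess stays open to it. Array scaling could not be judged, because RMA had already made the array distributions nearly equal. Of the large changes, 87.6% were rises under quantile normalization and 87.9% with centred arrays. Yet these settings moved the median change from -0.051 only to -0.0483 and -0.0725. With neither a fold minimum nor adjustment of p the balance turned: at an unadjusted p under 0.05, 4651 probe sets were lower and 3891 higher, and every deficient clone lay lower at 12.6% of all probe sets and higher at 10.7%. A shift shared by most transcripts would be lost in RMA and stays open, and no biological explanation was tested, since the probe sets have no gene names here.

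A block of 200 consecutive probe set identifiers had a median change of 0.71 log2 units, with 101 probe sets called higher, and the next of 178 blocks had 0.05. All 4 deficient clones showed it, with medians from 0.63 to 0.87 above the control mean, and controls reached at most 0.03. Signal level is argued against, since the highest median of 10000 random sets with the same levels and the same pattern of repeats was 0.18. Identical values may be the source of the median change: 76 probe sets of the block repeat the values of another, and over its 130 distinct ones the median change was 0.0304, under the highest of other blocks at 0.05. Repeats also supplied most of the 101 calls, which came down to 32 distinct ones, and whether they are the whole source of the share called stays open: it was 24.6% of distinct probe sets (95% interval 17.5 to 32.9%), against at most 17.2% (11.8 to 23.7%) in another block, its neighbour, and nearly equal values were not collapsed.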

How the results depend on the processing

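Chosen after seeing the data were the collapse of identical values, the omitted identifier block, slide scaling, brightness, saturation and the authors' bound regions; under these, every count stayed within 1.5 times its value. So it did under quantile normalization, centred arrays, robust eBayes with trend and, for all clones against controls, array weights. Testing only probe sets above the median level gave 1780 lower calls for all clones, 1371 for shRNA 1 and 1435 for C4i2, and 111 higher for C4i2 against shRNA 1; leaving out those under the lower quartile gave 34 lower there. The filters change both the probe sets tested and the adjustment. An unadjusted p under 0.05 gave 3891 higher and 4651 lower; more calls follow by construction, but the balance turned from rises to falls and the cause was not tested. Asking for at least 1.5-fold left 516 lower. Without single lines, counts ranged from 831 to 1576 higher and 283 to 850 lower for all clones, 568 to 1522 and 106 to 847 for shRNA 1, 943 to 1006 and 324 to 332 for C4i2, and 26 to 126 and 0 to 29 between C4i2 and the shRNA 1 clones; most counts fell, but without C1i5 the lower calls were more, at 847 for shRNA 1 and 29 for C4i2 against shRNA 1. At 1.5-fold, the probe sets apart from other lines numbered 3411 in E14, 3512 in E1, 3432 in G8, 2690 in C1i5, 2628 in C1i6, 3427 in C1i9 and 4098 in C4i2. Of the 4 named probe sets, 3 passed under all 17 alternatives each. Promoters above the threshold numbered 1307 with 500 bp, 956 with the median over probes, 968 with a 1% tail and 50 with a score of at least 1. For ribosomal protein genes the shares were 34.1%, 22.9%, 29.2% and 8.33% in that order, and thus fell along with the number of all promoters. Housekeeping genes had 14.5% with 500 bp and 14.5% with the median over probes, and ribosome biogenesis 23.5% with the 1% tail; a score of at least 1 left 0% of housekeeping, ribosome biogenesis and pluripotency promoters. With normexp, 15.3% of bivalent and 8% of tissue-restricted promoters passed; the cause was not tested in any of these ChIP-chip changes. Over all lists, 254 shares stayed within the 95% interval and 46 did not. A stricter threshold lowers shares by construction, and a score of at least 1 left only 50 of all promoters. Part of the 46 therefore follows from the threshold alone and says nothing particular about a list. Of the list medians, 221 moved by less than 1 SD of the members and 4 by more. An SD of the members is wide, so a median can stay within it while its percentile moves far. With normexp, housekeeping went from percentile 100 to 60.1 and neural from 3.82 to 37.1. Not run were all alternatives for the Chd1 transcript, the gene list shifts and the relations of occupancy to expression, lists matched on expression, the correction for GC content and the second deposited ChIP-chip table. Median IP intensity was 434.5 over a background of 41, and single arrays per line limit what can be called. No paired analysis was possible because the labels give the groups no shared replicate numbers.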

Other observations

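The gene families in this part were chosen after seeing the data, as were the division by slide and the counts of identical values; the tests on upstream probes, brightness and shared probes were set down before their results were seen.

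Clustered histone genes formed the highest family on the ChIP-chip array: 53 of 56 were above the threshold, with a median of 0.98 log2 units. The 3 below it were H1f6 at 0.11, H2ac1 at 0.12 and H2bc1 at 0.16, which encode the testis histones H1t, TH2A and TH2B and lie on chromosome 13 like most of the others. Signal was raised far upstream of clustered histone starts, with a mean of 0.43 and a median of 0.25 in the farthest bin, which begins at -5000 bp. The average over all genes there was -0.02. Starts of neighbouring histone genes can lie in that bin, so signal between the genes of a cluster is not shown. Several other families also had medians above those of at least 99% of random lists. Anaphase-promoting complex promoters had a median of 0.30 with 7 of 13 above, led by Anapc5 at 1.24. Complex I subunits of the respiratory chain had 17 of 36 above (median 0.26), proteasome subunits 16 of 37 (0.25), mitochondrial ribosomal proteins 22 of 75 (0.18) and translation initiation factors 15 of 51 (0.18); RNA polymerase II subunits had 5 of 11 above, with a median of 0.12 within the random range (percentile 91.8).

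Zinc finger genes with Zfp symbols had 59 of 238 promoters above the threshold and a median of 0.14, above all 10000 random lists. By contrast, 0 of 43 keratin genes (median -0.14), 0 of 32 Hox genes (median -0.04), 1 of 56 cytokine and chemokine genes and 8 of 736 olfactory receptor genes were above it. Olfactory receptor promoters had a median of 0.03, close to that of all promoters, while keratin and Hox promoters lay under it. In the authors' annotation, probes of divergent promoters lay in bound regions in 3.53% of cases, other promoter probes in 1.32% and probes inside genes in 0.767%.

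High scores at histone and ribosomal protein genes could arise from cross-hybridisation, since both have many near-identical copies. That is argued against by probes 100 to 1000 bp upstream of the start, outside the transcribed part: their median was 0.52 for ribosomal protein genes and 1.17 for histone genes, where random lists had 95th percentiles of 0.15 and 0.13. A histone gene's upstream probes can lie in a neighbour, but over those near 1 gene alone the median of 22 histone genes was 1.13. Probe brightness is argued against by medians of 0.29 and 0.95 with its trend removed, a single slide by the lower of the ribosomal protein medians on the slides, 0.29, and sharing of probes between neighbours by a histone median of 0.95 over probes of 1 gene alone. Base composition of the probes and unspecific pull-down of open chromatin stay open, since no ChIP without antibody or in Chd1-deficient cells was analysed here; Chd1 occupancy that goes with high transcription is a hypothesis left untested.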
